A study of Populus trichocarpa with 36 samples.

How the data were processed

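RNA from developing xylem of 36 trees was hybridised, 1 Cy3-labelled sample per array, to NimbleGen 12-plex poplar arrays, per the labels' protocols. The 17 genotypes with 2 trees carry the comparisons; the trees are biological replicates per the labels, and trees of 1 genotype are clones, so the genotype was the unit of replication between trait classes. HOMB21-1 and JASP30-4, with 1 tree and no class, entered no comparison. Slides, numbered 1 to 3, were read from the array names, as was a letter R in 4 names, whose meaning is not given in the sources used here.

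The values come in 2 versions. The per-array files hold 1 intensity per feature on a linear scale, per the file headers, together with the number of probes behind it and a further quantity of unstated meaning that was not used. The deposited series value table holds log2 values of the same arrays, a scale read from its values. RMA is named, without a version, in the submitters' processing notes; the genome build and the background correction are not given in the sources used here. The deposited values were already normalized between arrays: the same rank differed between arrays by a median coefficient of variation of 0.956% on the linear scale. For features with 1 or 2 probes the table equalled log2 of the per-array intensity within 0.001 in all features. For all 38109 features with 3 probes it did not, with a correlation over features of 0.845 to 0.859 per array; how the authors summarised 3 probes in either version is not given in the sources used here. Log2 of the per-array intensity was taken as the main version after the files were opened and before any comparison was fitted, and the table as the alternative.

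Of the 49476 entries of a file, 2 were left out of the tests: a control made of random-sequence probes, kept as a reference level, and an entry that repeats the header word. No filter on dim features was applied in the main tests. For each trait, log2 values were averaged over the 2 trees of a genotype and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with class as high, low or not classed and the share of the genotype's arrays on slides 1 and 2 as covariates. Differences are high minus low; for pairs of traits they are the class named first as high minus the class named first as low. Genotype differences were tested with limma's moderated F statistic on the 34 arrays, with slide as a covariate. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Tree-to-tree resemblance was the highest Pearson correlation of an array on slide-adjusted, feature-centred values, tested with 100000 permutations of the genotype labels. Files were read with data.table version 1.17.8 and jsonlite 2.0.0, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The tests, their samples and covariates, the rule for named features and most alternatives were fixed before the data were examined. That rule took, per trait and direction, up to 8 features of the largest difference among those past the threshold and otherwise filled up to 4 with those of smallest p, and for genotypes 10 by p and 10 by range. It was shortened to 2 per direction, and to 2 by p and 2 by range for genotypes, once it was found that no feature could be named.

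The 23 gene lists fixed beforehand (wood formation pathways, hormones, other cell types and harvest state) were not tested, because 0 of the features matched an identifier in the reference gene table and 0 list identifiers matched a feature; members of cell types other than xylem were therefore not measured here.

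On simulated data with 200 changed features per trait, made from the residual spread of each feature as independent noise, a 2-fold difference was recovered for 85.1% (glucose) to 95.5% (hemicellulose) of the changed features in the single-trait comparisons, each over 49474 features. Of the 172 calls made there for alpha cellulose, 15 were of unchanged features. In the genotype test a spread between genotypes of 0.5 log2 units (SD) was recovered for 76.1% of features. Since 200 features changed at once ease the Benjamini-Hochberg threshold, these shares overstate the recovery of a lone change. The simulated folds are of array signal, not of transcript level. The median standard error of a difference was 0.11 log2 units for density and 0.12 for glucose. The number of arrays, and with it that of genotypes, limits the precision. Alternatives covered the slide term, the unit of replication with and without a replicate block, the samples in the fit, a filter on dim features, median centring, quantile normalization, the other version of the values, the threshold, each slide alone, arrays with R in the name, and leaving out each genotype or array. Genotype means of named features were compared with Dixon's critical values, and trait comparisons with up to 100 splits of the classed genotypes, the real one included.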

Results

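Transcript levels were measured in developing xylem, the differentiating wood tissue under the bark, of natural black cottonwood (Populus trichocarpa) trees that grew side by side in 1 common garden. The 36 single-colour arrays, 12 on each of 3 slides, covered 19 genotypes, of which 17 were sampled as 2 trees each and 2, HOMB21-1 and JASP30-4, as 1 tree each. The submitters had placed the genotypes at the high or the low extreme of wood density, alpha cellulose, hemicellulose (as xylose), lignin and glucose. The comparisons therefore ask which transcripts differ between trees with contrasting wood, and how strongly the genotypes differ from each other. Each array gave 49474 gene model features, measured by 1 probe (2058 features), 2 probes (9307) or 3 probes (38109). The median level of an array lay between 10.16 and 10.22 on the log2 scale. A control of many probes, named in the files as random sequence, averaged 10.18 ± 0.03 (SD, n = 36), so that it lay in the middle of the measured features. In all 36 arrays 32.4% of the features stood above this control and 32.9% below it. The files do not pair the features with gene names, so features are given by identifier, with at most 2 in each direction of a comparison. Some of the chosen features are described without their identifier.

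The wood trait classes were linked across the genotypes. All 13 genotypes classed for both alpha cellulose and lignin had opposite classes, and all 12 classed for both alpha cellulose and glucose had the same class. Density went with alpha cellulose in 11 of 14 genotypes and against lignin in 11 of 14. Hemicellulose went against alpha cellulose in 7 of 10 genotypes and with lignin in 7 of 10. The comparisons of alpha cellulose, lignin and glucose thus rest largely on the same genotypes and are not independent of each other.

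The first question was whether the 2 trees of a genotype resembled each other. Of the 34 arrays of the 17 genotypes, 23 had their highest correlation with the other tree of the same genotype (one-sided permutation test of the genotype labels, p = 1e-05, the smallest that 100000 permutations can give). The highest count in the permutations was 12. The correlation between the 2 trees, over all features after removal of slide differences and centring of each feature, had a median of 0.271 over the genotypes, against a median of -0.0434 between arrays of different genotypes. It was highest in KLNE20-5 (r = 0.515), SQMC25-2 (r = 0.474) and LONG29-2 (r = 0.462). In HOMA21-4 (r = -0.0718), DEND17-5 (r = -0.00226) and NBON29-4 (r = 0.0348) the whole profile of 1 tree did not resemble that of the other. The closest pair of arrays from different genotypes was DEND17-5 tree 1 and HOMA21-4 tree 2 (r = 0.516). These correlations are across features, which are not independent replicates.

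**Figure D1:**
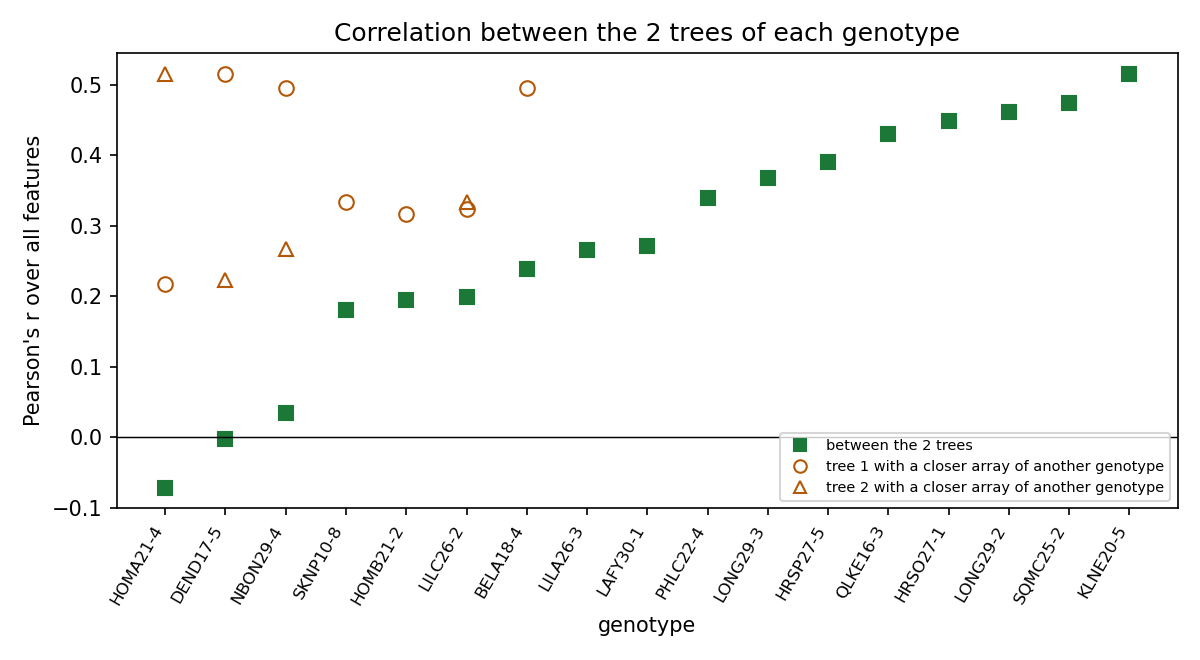
Pearson's r between the 2 trees of each of the 17 genotypes over 49474 features (squares, y axis), with genotypes on the x axis in order of that value. Open symbols mark trees whose closest array belonged to another genotype and give that higher correlation; 11 arrays have one, including all 6 of HOMA21-4, DEND17-5 and NBON29-4.

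Genotypes differed at 1908 features, 3.86% of those measured (limma moderated F test over 17 genotypes, Benjamini-Hochberg adjusted p under 0.05). Between the highest and the lowest genotype the median range of these features was 1.51 log2 units, and 1717 of them spanned more than 1 log2 unit. The feature gw1.6246.4.1 had the widest range, from 13.00 in HRSP27-5 to 4.76 in SQMC25-2 (limma adjusted p = 1.08e-12), while the 2 trees of a genotype differed by a median of 0.14 log2 units. SQMC25-2 stood alone at the low level, and the other 16 genotypes lay at 9.53 or higher. The feature gw1.XVIII.1382.1 had the smallest p (limma adjusted p = 1.48e-13) and fell into 2 levels: 7 genotypes lay at 4.65 or lower and 10 at 8.57 or higher. The feature gw1.12592.5.1 ranged over 7.05 log2 units, from 11.20 in PHLC22-4 to 4.15 in DEND17-5 (limma adjusted p = 7.85e-06), although the 2 trees of KLNE20-5 differed by 3.97 at this feature. Each of these features is measured by 1 probe, and their low levels lie far below the random-sequence control at 10.18, so that the ranges are differences in array signal and give no fold in transcript level.

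**Figure D2:**
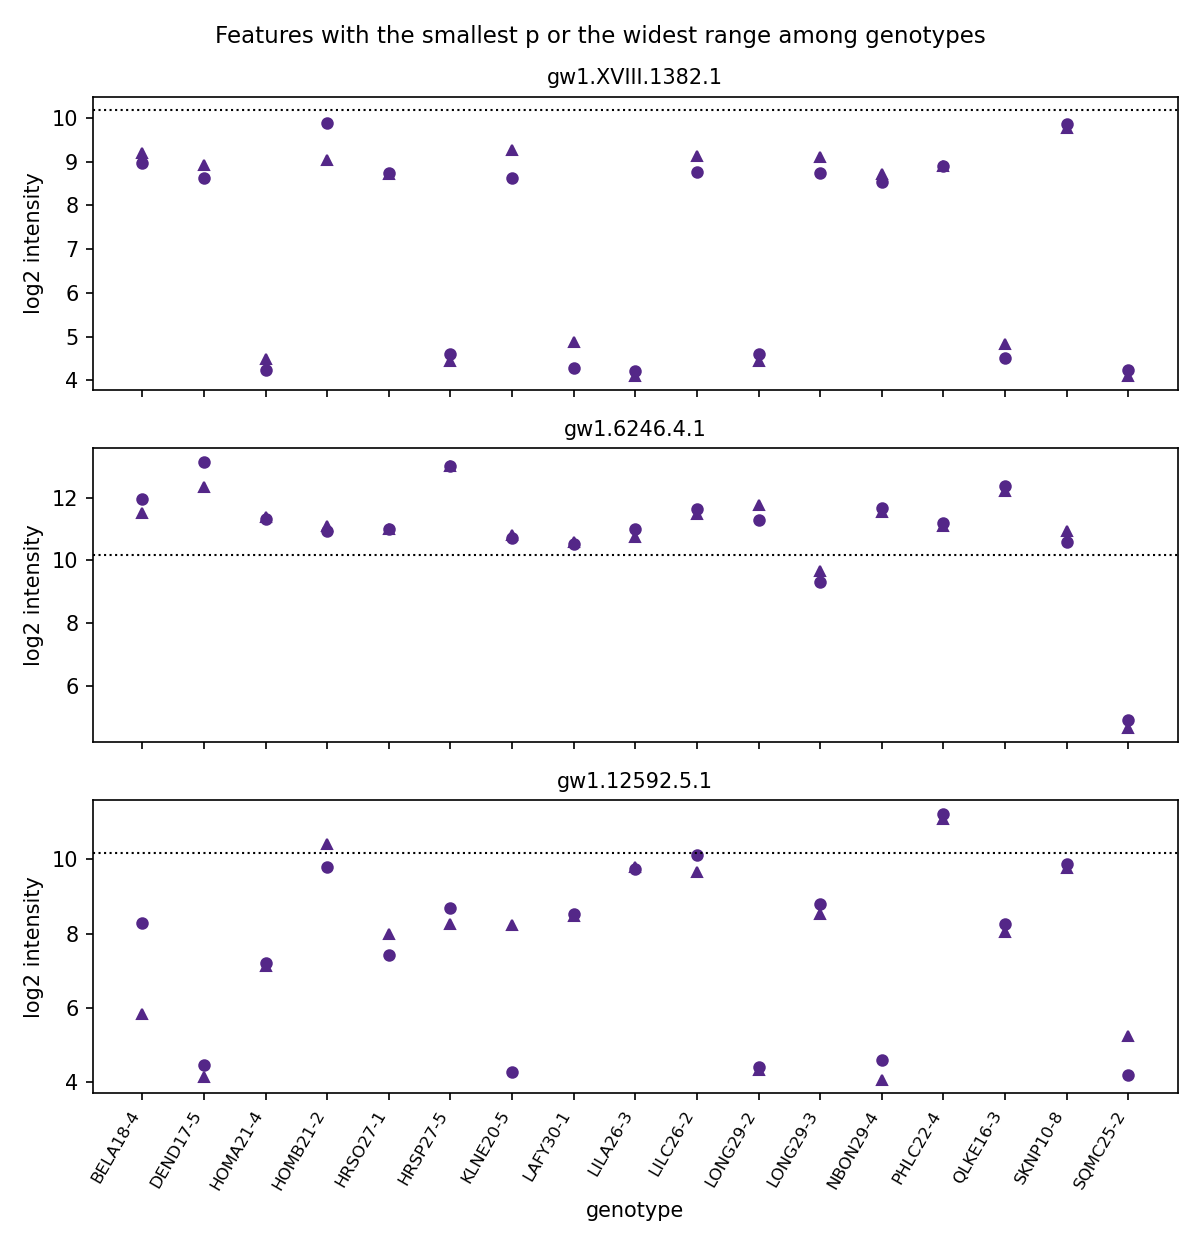
Log2 intensity (y axes) in the 17 genotypes (x axis) of the features with the smallest p or the widest range among genotypes; circles are tree 1, triangles tree 2 and the dotted line is the mean of the random-sequence control, 10.18. The trees of a genotype lie close together, apart from KLNE20-5, BELA18-4 and SQMC25-2 at gw1.12592.5.1, while genotypes lie up to 8.24 log2 units apart.

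The genotype differences were spread over the collection. LILA26-3 was the genotype farthest from the median of the 17 at 204 of the 1908 features (10.7%), followed by LONG29-2 at 178 (9.33%), where an even share would be 5.88%. LILA26-3 tree 1 had the highest median (10.22) and the highest random-sequence control (10.27) of the arrays and the lowest score on the second principal component (-0.664), and both LONG29-2 arrays lay on slide 1 and are among the 4 with R in the name. HOMB21-2 was the farthest at 26 (1.36%) and SKNP10-8 at 42 (2.20%), and HOMB21-2 tree 1 had its highest correlation with SKNP10-8 tree 1 (r = 0.317). Whether a wrong label or a mixed signal lowers these 2 shares was not tested. The farthest genotype lay below the median at 1237 features (64.8%) and above it at 671 (35.2%). For the median feature, 13.2% of the variance lay between genotypes, as an intraclass correlation of 0.132 (0.190 in the series value table). For the median of the 1908 it was 0.707, which is high by selection, since these were called on the same arrays. Differences between slides passed the same threshold at 12 features. The count of genotype differences depended on which of the 2 deposited versions of the values was used: 1762 of the 1908 features were also called in the series value table, which called 6236 in all. It was also higher, 5115, with the score of the first principal component as a covariate, a component that held 20.7% of the variance and of whose own variance 69.2% lay between trees of the same genotype; both alternatives were added after seeing the data.

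**Figure D3:**
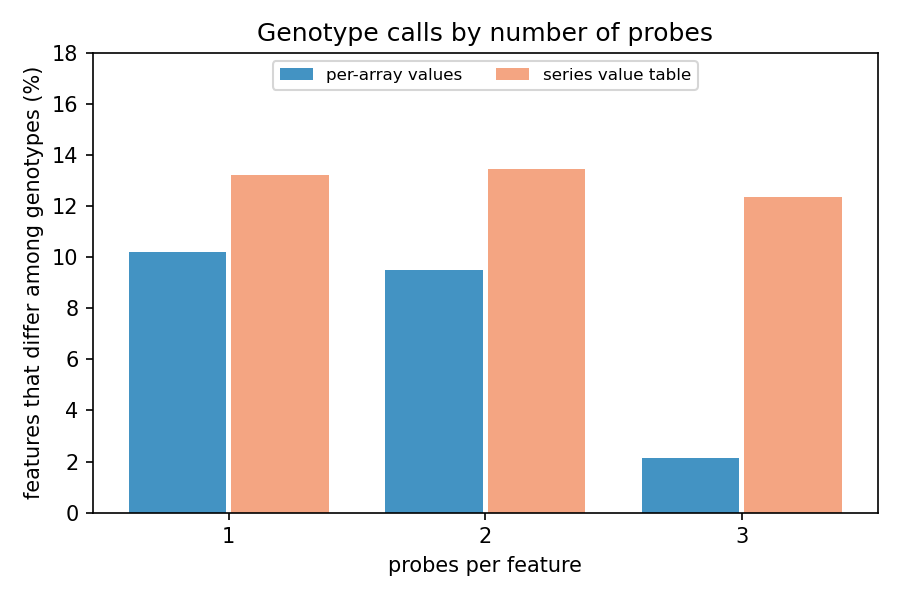
Percentage of features that differ among genotypes (y axis) by number of probes per feature (x axis), for the per-array values and for the series value table. In the per-array values 10.2% of 1-probe, 9.52% of 2-probe and 2.13% of 3-probe features were called, against 13.2%, 13.5% and 12.4% in the table.

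Alpha cellulose is the cellulose fraction that remains undissolved in strong alkali. Of the 49474 features, 1 differed between the 7 high and the 7 low genotypes. The feature fgenesh4_pg.C_LG_VI001909, measured by 2 probes, was higher in high alpha cellulose genotypes, at 10.17 ± 0.20 (SD, n = 7), than in low ones, at 9.25 ± 0.16 (SD, n = 7). With slide in the model the difference was 1.07 ± 0.12 log2 units of array signal (SE; limma, Benjamini-Hochberg adjusted p = 0.00242). Each of the 7 high genotypes lay above each of the 7 low ones, and the level was close to or below that of the random-sequence control. The feature second in order of p, given without its identifier, differed by -0.57 ± 0.12 log2 units (SE), high minus low, and did not pass the threshold. It gained a call in 1 of its 15 alternatives (lowest limma adjusted p = 0.0139). That fit took every array as an independent sample, and so counted the 2 trees of a genotype as independent. Among the features next in order of p, the values of gw1.VIII.605.1 differed by 0.42 ± 0.09 log2 units (SE) and those of fgenesh1_pg.C_LG_IX000006 by -1.32 ± 0.27, high minus low, and these did not pass the threshold (limma adjusted p = 1.00 for each). The former ran from 0.12 (within slide 1) to 0.56 (within slide 3) over its alternatives, with 0.13 in the series value table and 0.24 without a slide term, and the latter from -1.45 (within slide 2) to -0.61 (within slide 1), with -0.85 without a slide term. Within the slides the difference of fgenesh4_pg.C_LG_VI001909 was 0.93 ± 0.17 log2 units on slide 1 (5 high and 2 low genotypes), 0.82 ± 0.17 on slide 2 (4 and 4) and 1.28 ± 0.18 on slide 3 (3 and 6), the same direction in each, and did not pass the threshold in any single slide (lowest limma adjusted p = 0.155). The feature was chosen on these same arrays and genotypes recur between slides, so the shared direction is no independent check. The call held in each of 17 fits that left out 1 genotype (highest limma adjusted p = 0.0389). Over the comparison, 98.7% of the features had a 95% interval of the difference in array signal that lay within 2-fold in either direction. At features near or below the random-sequence control this does not bound the difference in transcript level.

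**Figure D4:**
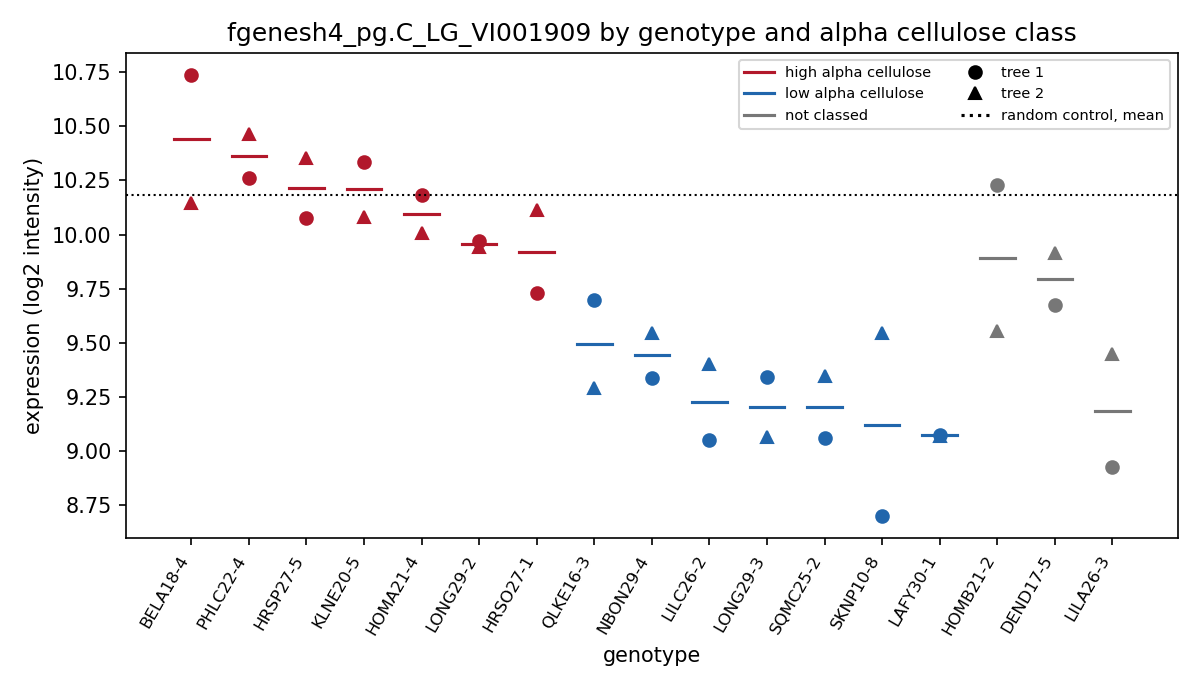
Log2 intensity (y axis) of fgenesh4_pg.C_LG_VI001909 in the 2 trees of each of 17 genotypes (x axis), coloured by alpha cellulose class; short lines are genotype means and the dotted line is the mean of the random-sequence control. Means of the high class run from 9.92 to 10.44 and those of the low class from 9.07 to 9.49.

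Lignin is the phenolic polymer of the wood cell wall. The same feature, fgenesh4_pg.C_LG_VI001909, was the 1 feature that differed between the 7 high and the 8 low lignin genotypes, in the opposite direction: it was at 9.25 ± 0.16 (SD, n = 7) in high lignin and at 10.12 ± 0.22 (SD, n = 8) in low lignin genotypes. Each of the 8 low genotypes lay above each of the 7 high ones. The difference, high minus low, was -0.97 ± 0.13 log2 units (SE; limma adjusted p = 0.0295). The values of fgenesh4_pg.C_scaffold_6462000001 differed by 1.34 ± 0.27 log2 units, those of estExt_fgenesh4_pm.C_860049 by 0.55 ± 0.12 and those of fgenesh4_pg.C_LG_I002083 by -0.80 ± 0.16, and these did not pass the threshold (limma adjusted p = 1.00 for each). Over their alternatives these ran from 1.07 (without a slide term) to 2.00 (series value table), from 0.29 (without a slide term) to 0.59 (within slide 3) and from -0.95 (within slide 3) to -0.60 (within slide 1). A call was gained by fgenesh4_pg.C_scaffold_6462000001 in 2 of 15 alternatives (lowest limma adjusted p = 0.0206) and by fgenesh4_pg.C_LG_I002083 in 1 of 15 (limma adjusted p = 0.0207). These calls arose only in fits that take each array as a sample. There the 2 trees of a genotype count as independent or share 1 low correlation set for all features. Within the slides the difference of fgenesh4_pg.C_LG_VI001909 was -0.85 ± 0.20 on slide 1 (2 high and 6 low genotypes), -0.80 ± 0.12 on slide 2 (5 and 5) and -1.28 ± 0.24 on slide 3 (5 and 3), and did not pass the threshold in any single slide (lowest limma adjusted p = 0.205). The call for lignin ended in 13 of the 17 fits that left out 1 genotype each (highest limma adjusted p = 0.391, without BELA18-4) and was kept without DEND17-5, HOMB21-2, LILC26-2 or NBON29-4. Its difference in the fits that left out 1 genotype ran from -1.03 to -0.90. It also ended without the arrays with R in the name (-1.01; 0.0828), in the series value table (-0.97; 0.0586) and, in alternatives added after seeing the data, with the first principal component (-0.95; 0.126) and without HOMA21-4, DEND17-5 and NBON29-4 (-1.04; 0.110), and over its alternatives the limma adjusted p ran from 4.21e-05 to 1.00.

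Hemicellulose, measured as xylose, divided 5 high from 7 low genotypes. The feature eugene3.02280004, measured by 3 probes, was lower in high hemicellulose genotypes, at 6.14 ± 0.27 (SD, n = 5), than in low ones, at 6.88 ± 0.33 (SD, n = 7), a difference of -0.76 ± 0.09 log2 units (SE; limma adjusted p = 0.0093), and 6 of the 7 low genotypes lay above each of the 5 high ones. It was the 1 feature past the threshold, with 3461 at an unadjusted p under 0.05. Both levels lie far below that of the random-sequence control. The feature second by p among those higher in high hemicellulose genotypes, given without its identifier, differed by 0.47 ± 0.08 log2 units (SE, limma adjusted p = 0.428). The values of fgenesh1_pg.C_LG_XI000828 differed by 0.70 ± 0.12 log2 units (limma adjusted p = 0.428) and those of eugene3.110740001 by -0.47 ± 0.09 (limma adjusted p = 0.469), short of the threshold. The former was 0.85 within slide 1 and 0.09 ± 0.21 (SE) within slide 3, and the latter -0.16 and -0.79. Within the slides the difference of eugene3.02280004 was -0.90 ± 0.19 on slide 1 (3 high and 4 low genotypes; limma adjusted p = 1.00) and -0.56 ± 0.17 on slide 3 (3 and 4; limma adjusted p = 0.228), and slide 2 held 1 high genotype, too few for a value. The call was not made in the series value table (difference -0.59; limma adjusted p = 0.316), without a slide term (-0.74; 0.764), among the 2 classes alone (-0.76; 0.177), with each array an independent sample (-0.74; 0.18), without the arrays with R in the name (-0.80; 0.0683) or without LILA26-3 (-0.59; 0.465), while 4 features passed without LONG29-2. It also ended in alternatives added after seeing the data, with the first principal component (-0.72; 0.0787) and without HOMA21-4, DEND17-5 and NBON29-4 (-0.75; 0.0623), and over its alternatives the limma adjusted p ran from 0.0093 to 1.00.

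Wood density separated 7 high from 8 low genotypes, and 0 of the 49474 features passed the threshold (limma, Benjamini-Hochberg adjusted p under 0.05), with 1666 features (3.37%) at an unadjusted p under 0.05, where 5% would arise by chance. The features with the smallest p were fgenesh4_pg.C_LG_IV000586, at 9.74 ± 0.08 (SD, n = 7) in high and 9.26 ± 0.26 (SD, n = 8) in low density genotypes, and fgenesh1_pg.C_scaffold_3497000001, at 12.42 ± 0.15 (SD, n = 7) and 12.79 ± 0.12 (SD, n = 8). Their differences of 0.58 ± 0.10 and -0.43 ± 0.08 log2 units (SE), like those of fgenesh4_pg.C_scaffold_17737000001 (0.86 ± 0.18) and fgenesh4_pm.C_LG_I000354 (-0.44 ± 0.09), did not pass the threshold (limma adjusted p = 1.00 for each). Over the alternatives fgenesh4_pg.C_LG_IV000586 ran from 0.31 (series value table) to 0.68 (within slide 2), fgenesh1_pg.C_scaffold_3497000001 from -0.56 (within slide 3) to -0.23 (within slide 1), fgenesh4_pg.C_scaffold_17737000001 from 0.47 (without a slide term) to 1.06 (within slide 2) and fgenesh4_pm.C_LG_I000354 from -0.65 (within slide 1) to -0.03 (within slide 2). Within slides 1, 2 and 3 the number of features past the threshold was again 0, and it was 1 without LAFY30-1. For 99.1% of the features the 95% interval of the difference in array signal lay within 2-fold. At features near or below the random-sequence control this does not bound the difference in transcript level. In simulated data of the same design a 2-fold difference in array signal was recovered for 91.0% of the changed features and a 1.5-fold difference for 55.2%. There 200 features were changed at once, which makes the Benjamini-Hochberg threshold easier to pass, so these shares overstate the recovery of a lone change.

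Glucose divided 7 high from 7 low genotypes, with 0 features past the threshold in limma and 1468 (2.97%) at an unadjusted p under 0.05. The feature eugene3.03300004 had the largest difference among those of smallest p, at 11.98 ± 0.35 (SD, n = 7) in high and 10.69 ± 1.16 (SD, n = 7) in low glucose genotypes, a difference of 2.02 ± 0.38 log2 units with slide in the model (SE; limma adjusted p = 1.00). The feature of smallest p among those lower in high glucose genotypes was the one second in order of p for alpha cellulose. It differed by -0.60 ± 0.12, short of the threshold, and gained a call in 3 of its 15 alternatives (lowest limma adjusted p = 0.00533). All 3 were fits that take each array as a sample, with or without the genotype as a random block. The values of estExt_Genewise1_v1.C_LG_VIII0441 differed by 0.54 ± 0.09 (limma adjusted p = 0.781), and those of gw1.218.28.1 by -1.12 ± 0.25 (limma adjusted p = 1.00). Over the alternatives the former of these ran from 0.21 (series value table) to 0.55 and the latter from -1.26 to -0.49 (within slide 2). Within slide 1 (6 high and 2 low genotypes) 2 features passed the threshold, with eugene3.03300004 at a difference of 3.11 log2 units (limma adjusted p = 0.000265), and within slides 2 and 3, where its difference was 1.63 and 0.99, the count was 0. The 2 low genotypes on slide 1, DEND17-5 and SQMC25-2, had the lowest means of eugene3.03300004 over both trees, 8.98 and 9.31. The other low genotypes lay at 10.47 to 11.94 and the high ones at 11.43 to 12.54, so the difference rests largely on these 2. With each array as a sample and the genotype as a random block, 3 features passed, including eugene3.03300004 (1.67, limma adjusted p = 0.046), whose limma adjusted p ran from 0.000265 to 1.00 over its alternatives. That fit set 1 correlation between trees, 0.138, for all features, while the intraclass correlation of eugene3.03300004 was 0.827. The 2 trees of a genotype were thus treated there as more independent than they were at this feature.

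The labels also class genotypes on pairs of traits, and these classes were used as labelled. Some genotypes in them have no single-trait class for a trait of the pair. These are HOMB21-2 for lignin, DEND17-5 and HRSP27-5 for hemicellulose, and LILA26-3 for density and alpha cellulose. Between 7 genotypes high in alpha cellulose and low in lignin and 7 of the opposite kind, fgenesh4_pg.C_LG_VI001909 was the 1 feature that differed, by 0.99 ± 0.13 log2 units (SE, limma adjusted p = 0.0235). These are the same 7 high alpha cellulose and 7 high lignin genotypes as in the single-trait comparisons, so the call is not an independent result. It ranked first by p, without passing the threshold, between genotypes high and low in both density and alpha cellulose (5 and 7 genotypes; 1.07 ± 0.17; limma adjusted p = 0.295). In that comparison 0 features passed, with 1533 at an unadjusted p under 0.05. The same count of 0 in limma was found for hemicellulose with lignin (3 high in both and 7 low in both; 2416 at an unadjusted p under 0.05), for density against lignin (6 and 6; 1304) and for alpha cellulose against hemicellulose (6 and 3; 2834). The call for alpha cellulose against lignin ended in 10 of the 17 fits that left out 1 genotype each and was kept without DEND17-5, HOMB21-2, HRSO27-1, LILC26-2, LONG29-2, NBON29-4 or QLKE16-3. A count of 0 became 1 for density with alpha cellulose without HRSP27-5 or without SQMC25-2, and for alpha cellulose against hemicellulose without QLKE16-3.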

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

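Tests chosen only after the result was seen were the position and mixing of HOMB21-2 tree 1 relative to SKNP10-8, the check of the 6 arrays of DEND17-5, HOMA21-4 and NBON29-4, the shared slide of arrays that match another genotype, and the gap between genotype means of fgenesh4_pg.C_LG_VI001909.

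In the low alpha cellulose class of 7 genotypes, LILC26-2 lay far from the others at the feature of smallest p among those lower in the high class, at 9.35 against 9.74 for the nearest and 10.01 for the highest. Its gap is 0.583 of the class range, above Dixon's critical value; of 40 classes examined 1 held such a genotype, where chance gives about 5%.

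Genotypes differed at 1908 features, and of 100 pairings of the 34 arrays 1, the real one, gave as many (highest other 25), which excludes chance pairing. Sequence differences under a probe remain open as a source: a call was 5.22 times as likely in odds (95% interval 4.45 to 6.12) for 1-probe as for 3-probe features in the per-array values, but 1.08 times (0.947 to 1.23) in the series value table, so that this difference rests on the version of the values. Features below the random-sequence control were called more often than those above it (odds ratio 1.67, 95% interval 1.52 to 1.84), so hybridization differences at dim features stay open too. Heritable differences in transcript level, which the design names, were not separated from these here.

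The mislabelling of samples was examined for the 11 arrays that resembled another genotype more than their own second tree. On 35 features with 2 separate levels, chosen without the labels, 30 of 34 arrays matched their own genotype, among them 6 of the 6 arrays of DEND17-5, HOMA21-4 and NBON29-4. This argues against a wrong label for those, with a wide margin in HOMA21-4 tree 1 (own r = 0.763, highest other 0.507). The margin was narrow in DEND17-5 tree 1 (0.554 against 0.512) and NBON29-4 tree 2 (0.547 against 0.512). Of the 4 that did not match, HOMB21-2 tree 1 and SKNP10-8 tree 1 are among the 11. LILA26-3 tree 2 and SKNP10-8 tree 2 matched their own genotype over all features (r = 0.266 and r = 0.180). A wrong label stays open for these 4. Features with 2 levels were also taken with a gap of at least 0.6 log2 units between the levels. At 49 of these the second trees of HOMB21-2 and SKNP10-8 differed by at least 2 times that gap. There HOMB21-2 tree 1 had a median position of 0.517 (95% interval 0.281 to 0.751) between SKNP10-8 at 0 and its own second tree at 1 (0.693 with a gap of 0.8). This argues against a plain swap of HOMB21-2 tree 1 with SKNP10-8. With the gap of 0.6 its position was still the lowest of 272 such pairs (median 0.917), and with 0.8 it ranked 2 from the lowest. With 0.6, 34.7% of positions lay near SKNP10-8, 36.7% near its own second tree and 28.6% in between. With 0.8 these shares were 22.2%, 44.4% and 33.3%. The intermediate share ranked 8 from the highest with 0.6 and 5 with 0.8, so other pairs had higher shares. Whether signal of 2 genotypes was mixed stays open. Of the 11 matches, 36.4% lay on the same slide against 32.4% by chance (exact binomial p = 0.5, one-sided), which decides nothing, since the matches were found on slide-adjusted values. The first principal component loaded less on features below the control than above it (ratio of mean squared loadings 0.715, 95% interval 0.698 to 0.735). That component was not tied to the 11 matches, and loadings grow with the spread of a feature. Background signal as a source of the matches therefore stays open. A difference between trees at sampling was not tested.

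For fgenesh4_pg.C_LG_VI001909, 0 of the 14 classed genotypes ended the call for alpha cellulose when left out, so no single genotype carries it. The largest gap between neighbouring genotype means was 0.219 of their range, which argues against 2 sharp probe-sequence levels. It lay between 8 lower and 9 higher genotypes and also divided the low from the high alpha cellulose class, so 2 less sharp levels stay open. Chance division of the genotypes was not excluded: 7 of 100 splits of the 14 genotypes, the real one included here and below, gave at least 1 feature for alpha cellulose (real count 1, highest other 1), 8 of 100 for lignin (1, highest other 5) and 8 of 100 for alpha cellulose against lignin (1, highest other 2). Whether the feature follows wood composition therefore stays a hypothesis.

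Splits of the classed genotypes do not exclude chance for hemicellulose, where 11 of 100 gave as many features (real count 1, highest other 4). For the comparisons with a count of 0 in limma every split gives as many by construction, so these splits say nothing about chance: 100 of 100 for density (1666 features at an unadjusted p under 0.05; highest other 1), glucose (1468; 3), density with alpha cellulose (1533; 1), hemicellulose with lignin (2416; 36) and density against lignin (1304; 3), and 84 of 84 for alpha cellulose against hemicellulose (2834; 6). The 36 features of 1 split of hemicellulose with lignin may reflect a structure of the samples, but this was not tested, nor what the genotypes of that split share.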

How the results depend on the processing

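Alternatives for gene lists and cell type markers were not run, since no feature could be named, and slide 2 held too few high hemicellulose genotypes for a value. Alternatives with the first principal component, without 3 genotypes of low tree-to-tree correlation, and with the series value table for genotypes and pairs of traits were added after seeing the data. Of the alternative values of named features 0 changed direction and 10 gained a call. The gained calls arose only in fits that take each array as a sample or, for glucose, within slide 1. The value of a genotype feature is a range and cannot change direction. Trait features were chosen by p or size on these same arrays, which favours an unchanged direction. The count of 0 is therefore no test of stability. All 33 lost calls were of the features called between trait classes: fgenesh4_pg.C_LG_VI001909 lost the call for alpha cellulose in 3 of 15 alternatives and in 0 of 17 fits that left out 1 genotype, and for lignin in 7 of 15 and 13 of 17, and eugene3.02280004 for hemicellulose in 9 of 14 and 1 of 17. The cause was not tested unless stated. The call for alpha cellulose stayed at 1 feature except with every array an independent sample (3), with features above the median level alone (0, which leaves out fgenesh4_pg.C_LG_VI001909), and within slides 2 and 3 (0 in both); within slide 1 the 1 feature was another. For hemicellulose the count was 0 without a slide term, among the genotypes of the 2 classes, above the median level, without the arrays with R in the name, within slide 1, with the first principal component and without the 3 genotypes, 2 with arrays and a random genotype block, 14 within slide 3, and 1, another feature, in the series value table. For lignin it was 0 above the median level, in the series value table, without the arrays with R in the name, within each of slides 1, 2 and 3, with the first principal component and without the 3 genotypes, 2 with a random genotype block and 5 with every array independent. For glucose it was 3 with a random genotype block, 4 with every array independent and 2 within slide 1; for alpha cellulose against lignin it was 0 without the 3 genotypes. Fits with a random genotype block set 1 correlation between trees for all features, which is too low for features whose trees resemble each other closely. Limma settings with a count of 0 held 658 to 6659 features at an unadjusted p under 0.05. Leaving out each genotype in turn gave 0 to 1 features for density (1 without LAFY30-1), lignin (1 without DEND17-5, HOMB21-2, LILC26-2 or NBON29-4), density with alpha cellulose (1 without HRSP27-5 or SQMC25-2), alpha cellulose against hemicellulose (1 without QLKE16-3) and alpha cellulose against lignin, 0 to 4 for hemicellulose (0 without LILA26-3, 4 without LONG29-2), 1 to 1 for alpha cellulose, and 0 to 0 for glucose, hemicellulose with lignin and density against lignin. Genotype differences numbered 745 above the median level (fewer features tested; 721 of them shared), 858 at an adjusted p under 0.01, 6236 in the series value table, 5115 with the first principal component, and 1395 to 2556 without each array in turn (lowest without KLNE20-5 tree 2, highest without DEND17-5 tree 2). Arrays matching their own genotype numbered 18 to 23. Tree numbers do not pair the samples: deviations of same-numbered trees correlated by a median of -0.0239 between genotypes (from -0.554 to 0.621). With tree number as a replicate block the counts were 0 for density, 1 for alpha cellulose, 2 for hemicellulose, 2 for lignin and 3 for glucose, and 1722 for genotypes. The random-sequence control lies at the middle of the features, which limits how far dim features can be read.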

Other observations

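The tests of neighbouring identifiers were written before their result was seen, and the test of the deposited versions and the linkage group shares were chosen after the data were seen.

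Among the features that differ among genotypes, those whose identifier spells out no linkage group were over-represented: they were called at a share of 4.57% of 28108 (odds ratio 1.60, 95% interval 1.45 to 1.76; Fisher's exact test, adjusted p = 1.93e-20 over 20 groups). Tested in the same way against all other features, the share was lower in linkage groups VI (1.81%, adjusted p = 0.000326), II (2.13%, adjusted p = 0.000392), XVI (1.94%, adjusted p = 0.0092) and I (2.81%, adjusted p = 0.0174), and the other 15 linkage groups did not pass. These comparisons include the features without a linkage group among the others, and no test was made among the linkage groups alone. An identifier that spells out no linkage group does not show that its gene model is unplaced. The number of probes was not taken into account, although 10.2% of 1-probe and 2.13% of 3-probe features were called. Whether these shares follow position or the number of probes was not tested.

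Structural differences that span several gene models were a candidate source of the genotype differences. Among 26413 features with ordered identifiers, 10 pairs of direct neighbours were both called, against a median of 9 when the calls were shuffled within a series (highest 21; permutation p = 0.398), so the calls did not cluster beyond chance. The genotype profiles of these pairs had a median correlation of 0.217 (95% interval -0.0653 to 0.445), across genotypes within pairs, which argues against neighbours that measure the same sequence.

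The genotypes with 1 tree and no trait class lay at opposite ends at fgenesh4_pg.C_LG_VI001909, with 10.53 in HOMB21-1 and 8.70 in JASP30-4.

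The per-array values may hold a median-type and the table a mean-type summary of 3 probes. The spread between features of 3 probes was 1.13 times as wide in the per-array values (95% interval 1.13 to 1.14), as that hypothesis needs, but no value per probe was analysed here. Of these features, 666 were called among genotypes in both versions, 4044 in the table alone and 146 in the per-array values alone.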
